A study of Mus musculus with 10 samples.

How the data were processed

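The study measured RNA from the RPE/choroid complex of mouse eyes, the retinal pigment epithelium with the vascular layer behind it. Per the labels, all 10 samples came from iDTR mice, which carry a Cre-dependent diphtheria toxin receptor, given diphtheria toxin by intraperitoneal injection. The series description gives daily toxin for 7 weeks for the mice with Cre; the same time is assumed for control. In the 5 samples called ADQ here the mice also carried adiponectin-Cre, so that the toxin acts on adiponectin-expressing fat cells; the 5 control samples lacked Cre. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that each sample came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

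Per the labels' protocols, tissue was taken into TRIzol, RNA was purified on NucleoSpin columns and cDNA was amplified by SMARTer. The submitters' processing notes name the GRCm38 build and the tools bcl2fastq, DRAGEN, edgeR and limma, with neither versions nor roles; the counting settings, including strand, are not given in the sources used here. The deposited count table holds whole-number counts per Ensembl gene and library, not normalized. It has 55774 entries for 55487 distinct genes, and the 287 repeated entries were removed. The authors' deposited table holds log2 CPM values per library, a log2 fold change and p-values, raw and adjusted, for 15860 distinct genes. Its log2 CPM values equal those recomputed from the counts with 0.5 added, apart from 1 constant per library; the spread around that constant was at most 2.9e-09. No column of per-sample values was left unused.

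Total counts ran from 43.6 M (M, mega) in ADQ 4 to 64.1 M in ADQ 5. At this depth the spread between samples, not counting error, limits most genes. Amplified reads carry no molecular identifiers here, so the limit that a count of 0 allows (3 counts in that library) covers counting error only. For every pair of libraries, within and across groups, a chi-square statistic was computed over genes with at least 500 counts in total. The smallest was 33.9 per degree of freedom, far above the value of sampling noise alone, so no library was a duplicate of another.

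Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). The filterByExpr defaults (minimum count 10, minimum total 15) kept 20684 genes. Libraries were scaled by TMM, and a robust quasi-likelihood fit with group as its single term was tested with Benjamini-Hochberg adjustment at 0.05. Fold changes are ADQ over control, and CPM values are TMM-scaled. Standard errors are the size of the log2 fold change over the square root of F. In all, 44 gene lists were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean over all 252 assignments of the 10 libraries, whose smallest p is 0.00794. Single values per library were compared by the same exact test.

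The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the adipocyte list, then up to 10 protein-coding genes per direction with a mean of at least 1 CPM, excluding predicted genes and antigen receptor segments. Those whose adjusted p stayed under 0.05 without any single library came first, ordered by size, and the remaining places went to the largest other changes that passed. From each list it took up to 4 members with the smallest p. Symbols and Ensembl identifiers come from the count table; positions come from GENCODE M21 on GRCm38, which holds 99.4% of the table's identifiers.

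The alternatives fixed in that way were other scalings (RLE, upper quartile, library size alone), no low-count filter or a stricter one (1 CPM in 5 libraries), DESeq2 1.42.0, voom with quality weights, a non-robust fit, each library left out, the replicate number as a block, rod or RPE marker level as a covariate, 1 surrogate variable (sva 3.50.0) and a test against a 1.2-fold change. Further alternatives were chosen after seeing the data. They were leaving out control 5 together with a rod covariate, a covariate for the trend with transcript length in each library, and 6 adipocyte markers alone. The split of the libraries that led to the length trend was also tried as a covariate while exploring, and is not reported because the split was chosen by its result. Those 6 markers were the ones that passed without control 5, so their difference is circular.

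The gene test was tested on simulated data with the real means, dispersions and library sizes, 20684 genes and 200 of them, all with a mean of at least 1 CPM, changed. For the ADQ against control comparison it recovered 32.8% of 67 genes changed 1.5-fold, 59.7% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, none in the wrong direction, with 7 unchanged genes called. A simulated 1.5-fold rise of the interferon list was called, with 0 of the other lists; genes were drawn independently of each other, so this does not test camera's preset correlation.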

Results

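Messenger RNA was profiled in the RPE/choroid complex of 5 control and 5 ADQ samples, the ADQ mice being built to lose adiponectin-expressing fat cells to diphtheria toxin. Libraries held 49.4 ± 1.21 M counts (M, mega) in control and 50.6 ± 7.93 M in ADQ (mean ± SD, n = 5 each), a difference of 1.22 M (exact permutation p = 0.921). Counts of the Y-linked gene Ddx3y ran from 1820 to 3275 and those of Xist, the X-inactivation transcript, from 6 to 30, so all 10 libraries had the pattern of male tissue.

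The comparison first asks whether the dissected tissue held the targeted cells. Some transcripts of fat cells were present at low level in 4 controls and had lower means in ADQ, with control 5 as an exception, but none of the list passed over all genes. Adipoq, which encodes adiponectin and whose promoter drives the Cre, had 177 to 402 counts in controls 1 to 4, 0 in control 5, and 8 to 77 in ADQ. The 0 allows up to 0.0624 CPM in that library by counting error alone. Cfd (adipsin) was at 39.9 ± 26.4 CPM in control and 4.16 ± 2.59 in ADQ (SD, n = 5), and at 2.66 CPM in control 5. Cidec, a lipid droplet protein, was at 4.91 ± 3.28 and 0.92 ± 0.503 CPM.

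None of the 12 adipocyte list members tested passed over all genes with edgeR, where Cidec had an adjusted p of 0.168 and Adipoq 0.369; 4 were lower when adjusted over the list alone. All 12 had a log2 fold change below 0, with a median of -1.11. Camera placed the list lower in ADQ (adjusted p = 5.7e-04), but adjusted p = 0.533 with an estimated correlation. The list mean differed by -1.01 log2 units (exact permutation p = 0.0873). Without control 5, 6 of 13 members tested fell: Adipoq (log2 fold change -2.56), Cidec (-2.71), Cfd (-3.57), Car3 (-2.20), Plin1 (-1.38) and Retn (-1.72). The list mean then differed by -1.42 (exact permutation p = 0.00794, the smallest possible). Control 5 had the lowest list mean of all libraries (0.62 log2 CPM), against 2.37 to 3.15 in the other controls and 0.79 to 1.91 in ADQ. Leaving it out thus separates the groups by itself, so this p and these 6 falls are no independent support. Lipe and Plin4, both also used outside fat, stayed near their control level. Their log2 fold changes were -0.08 and -0.20 with all libraries, and -0.08 and -0.16 without control 5.

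**Figure D1:**
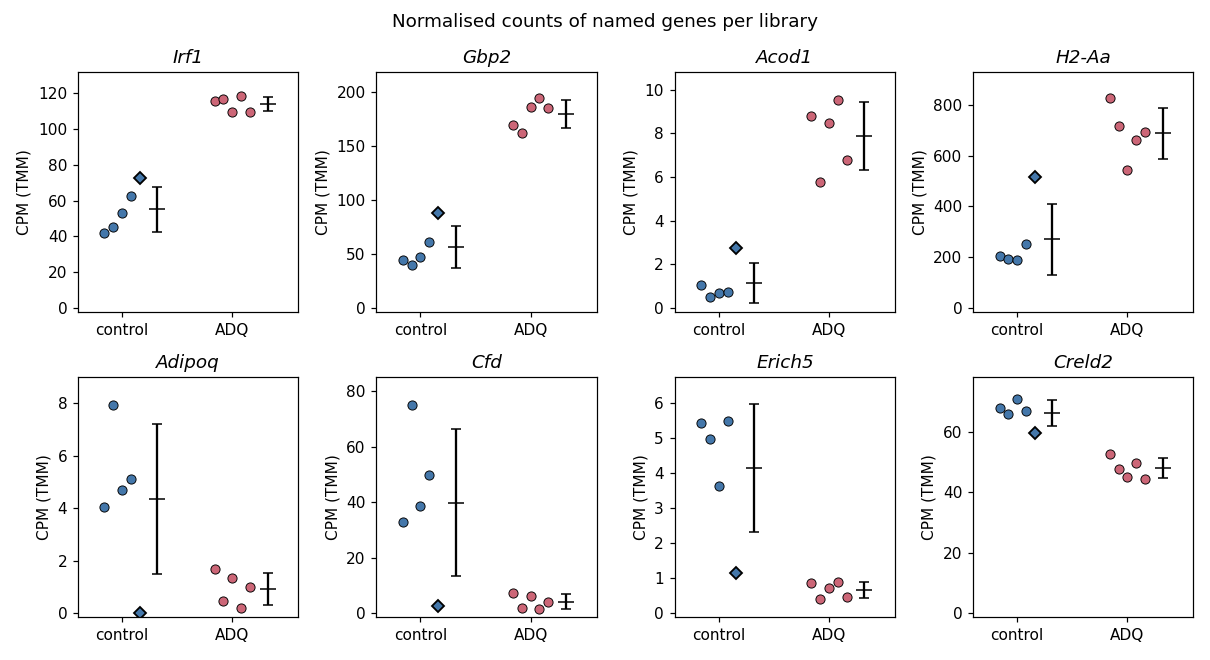
Normalised counts (CPM, TMM-scaled, linear axis from 0) of 8 genes in each library, control in blue and ADQ in red; diamonds are control 5, and the dash and bar beside each group are its mean and SD (n = 5). Irf1 runs from 109.6 to 118.5 CPM in ADQ and from 42.1 to 72.7 in control, and Adipoq is at 0 in control 5.

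The main comparison asks how gene expression in the RPE/choroid complex of ADQ differed from control. Of the genes fixed beforehand, 6 of 18 interferon response genes and 2 of 8 MHC class II genes rose in ADQ over all genes tested. Camera called both lists higher, but with an estimated correlation their adjusted p was 0.127 and 0.381. Irf1, an interferon-induced transcription factor, rose 2.07-fold, from 55.0 ± 12.6 to 114 ± 4.11 CPM (SD, n = 5; log2 fold change 1.05, SE 0.13, edgeR adjusted p = 0.00195). With edgeR 18 genes fell, 7 of them by at least 2-fold, but the number that fell was not stable. It was 266 with DESeq2, run without the edgeR count filter, 153 with voom and quality weights, and 32 with edgeR without a count filter.

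Of 20684 genes tested, 171 passed, 153 higher and 18 lower in ADQ; 2856 had an unadjusted p under 0.05. Of the 171, 85 rose at least 2-fold; 140 of the higher and 15 of the lower genes were protein-coding. The median log2 fold change of all genes was 0.01. Calls that held without any single library numbered 65, of which 62 were higher and 3 lower. Leaving out control 5 raised the count to 357 (316 higher, 41 lower), and 159 of the 171 were among them. Counts also moved by over 1.5 times without control 1 (96), control 4 (78), ADQ 2 (81), ADQ 3 (99) or ADQ 4 (87).

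The 10 largest rises that held without any single library, among protein-coding genes with a mean of at least 1 CPM, ran from 3.51- to 6.87-fold. Acod1, whose enzyme makes itaconate in activated macrophages, rose 6.87-fold (log2 fold change 2.78, SE 0.41, adjusted p = 0.00756), from 1.15 ± 0.915 to 7.88 ± 1.56 CPM. Acod1 (ENSMUSG00000022126) lies on chromosome 14 at 103046977 to 103056573. Il12rb1, a subunit of the IL-12 receptor, rose 5.10-fold. Tgtp2, an interferon-inducible GTPase, rose 4.81-fold from 28.5 ± 15.1 to 137 ± 27.2 CPM. Gbp5, Gbp8, Gbp9 and Gbp6, guanylate-binding proteins, rose 4.61-, 3.86-, 3.75- and 3.74-fold. Gbp8 (chromosome 5, 105014150 to 105139540) overlaps Gbp9 (105077630 to 105139539) on the same strand, and members of this family and Tgtp2 have close paralogs, so their separate values are uncertain. Gcsam, expressed in germinal centre B cells, Rasgrp1, a Ras activator of lymphocytes, and Tlr12, a Toll-like receptor, rose 4.77-, 3.66- and 3.51-fold.

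Of the 10 lower genes named here, Erich5 and Creld2 kept their call without any single library. Erich5 (chromosome 15, 34453305 to 34473892) fell 6.24-fold, from 4.13 ± 1.83 to 0.662 ± 0.23 CPM (log2 fold change -2.64, SE 0.40, adjusted p = 0.00756), with control 5 at 1.14 CPM. Controls 1 to 4 held 3.63 to 5.48 CPM, so control 5 was low here as it was in Adipoq. The fall of Erich5 is thus not separated from the difference in fat cell transcripts. Creld2, an endoplasmic reticulum protein induced by stress, fell 1.38-fold, from 66.2 ± 4.21 to 48.0 ± 3.3 CPM (adjusted p = 0.0132; at most 0.05 without any single library). Aldh3b2, Cldn3, Csrp3, Cyp4b1, Sostdc1, Wipf3, Cdk1 and Rnd2 also fell, each losing its call without at least 1 library. Of these, Aldh3b2 fell most (log2 fold change -3.75, adjusted p = 0.0355, up to 0.129 without 1 library), and control 3 held 10.9 CPM against 0.849 to 4.03 in the other controls. Csrp3, a muscle LIM protein, fell 3.44-fold; Cldn3, a tight junction protein, fell 3.89-fold. Cldn3 and Aldh3b2 order the 5 controls as the corneal and conjunctival keratin Krt5 does, so their falls are not separated from the difference in carried-over epithelium. Csrp3 orders the controls as the skeletal muscle list does, but in ADQ 2, 3 and 4 it was at 1.45 to 2.95 CPM while that list was at 6.49 to 6.59 log2 CPM, near the control mean of 6.52. Sostdc1, a secreted BMP antagonist abundant here, fell (log2 fold change -0.58) from 246 ± 25.8 to 164 ± 20.5 CPM.

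The interferon response list was higher by camera and fry. Of 18 members tested, 6 rose over all genes tested and 13 when adjusted over the list alone; 17 had a log2 fold change above 0, and the median was 0.56. Gbp2 rose 3.20-fold to 179 ± 13.1 CPM and Gbp3 2.99-fold to 79.9 ± 10.6 CPM. Camera gave an adjusted p of 1.5e-12 for this list, but adjusted p = 0.127 with an estimated correlation. Fry, which asks whether the genes move one way, gave an adjusted p of 0.00248. Control 5 lay above the other controls in Irf1 and Gbp2, at 72.7 and 87.6 CPM; without it 7 members rose.

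MHC class II genes, which present antigen to helper T cells, had the largest median rise among the lists that passed upward, 1.27. H2-DMb1 rose 1.76-fold (adjusted p = 0.011) and H2-DMa 2.45-fold (adjusted p = 0.0332, up to 0.0959 without 1 library), the 2 of 8 members that passed over all genes; 8 rose when adjusted over the list alone. H2-Aa was at 271 ± 140 CPM in control and 688 ± 102 in ADQ (adjusted p = 0.0574). Camera gave an adjusted p of 3.4e-10, but adjusted p = 0.381 with an estimated correlation, and fry gave 0.0144. Control 5 held 517 CPM of H2-Aa against 190 to 252 in the other controls, and without it 7 of 8 members rose. It had the highest mean of the controls in this list and in the interferon, lymphocyte and cytokine lists. Leaving it out thus widens these differences by itself, so the added rises are no independent support.

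Among immune cell markers, camera placed those of lymphocytes and NK cells and of macrophages higher in ADQ, while neutrophil markers did not pass (adjusted p = 0.499). Mast cell markers had a median log2 fold change of -1.01 (camera adjusted p = 0.0495, and 0.648 with an estimated correlation), with 0 of 7 passing. Their call held in 5 of 20 alternatives, not counting the estimated correlation (camera adjusted p = 0.121 without control 5). None of the 14 lymphocyte and NK cell markers rose over all genes tested, and 0 when adjusted over the list alone, while camera placed the list higher (adjusted p = 2.2e-05, but adjusted p = 0.467 with an estimated correlation). Cd3e, of the T cell receptor complex, was at 2.91 ± 2.96 CPM in control and 9.85 ± 2.05 in ADQ, and control 5 held 7.94 CPM. Without control 5, 6 of the 14 rose. Its list mean of 1.95 log2 CPM lay above that of ADQ 5 (1.86), so these rises are no independent support either. Of 16 macrophage and microglia markers, 2 rose, Aif1 1.90-fold and Adgre1 1.39-fold (Adgre1 up to an adjusted p of 0.144 without 1 library), and 4 when adjusted over the list alone (camera adjusted p = 0.00202; adjusted p = 0.533 with an estimated correlation); the median was 0.30, and without control 5 there was 1 rise. Of 20 cytokines and NF-kB targets, 2 rose, the adhesion molecule Vcam1 1.68-fold and the chemokine Ccl8 1.99-fold, both losing the call without 1 library (adjusted p up to 0.0567 and 0.117), and 6 rose and 1 fell when adjusted over the list alone. Camera gave that list an adjusted p of 4.6e-05 (adjusted p = 0.127 with an estimated correlation), and without control 5 there were 3 rises. C4b, a complement component, rose 1.47-fold (adjusted p up to 0.095 without 1 library), while the complement list did not pass (camera adjusted p = 0.139).

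**Figure D2:**
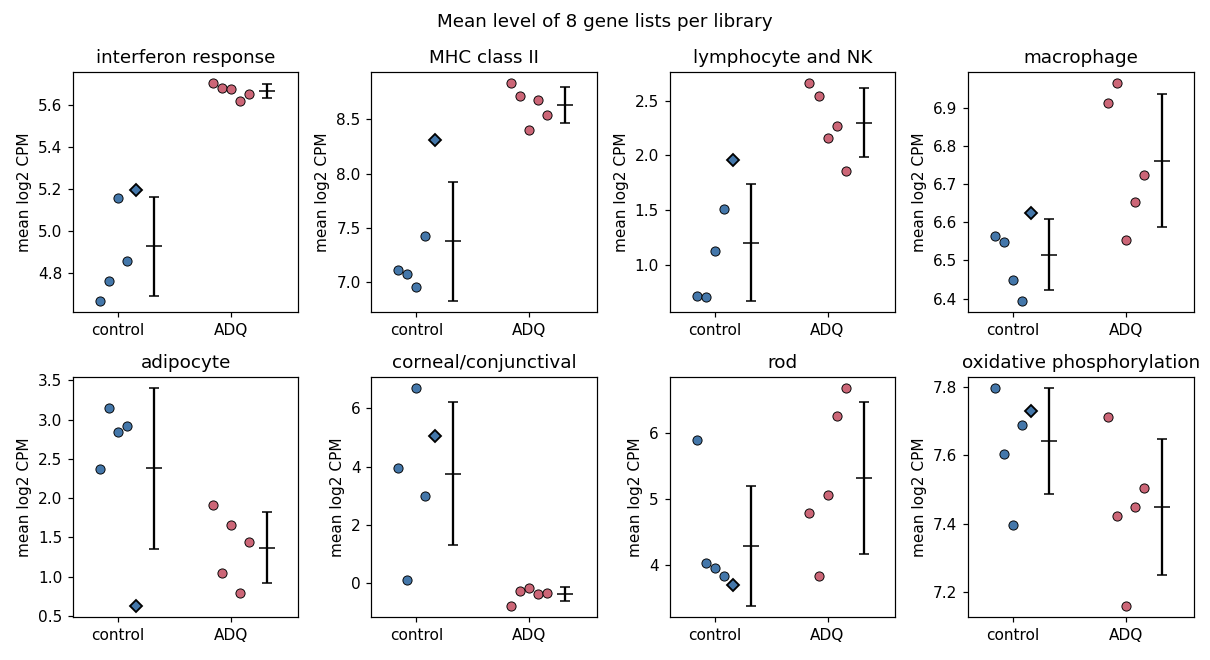
Mean log2 CPM of 8 gene lists in each library (the axes of the panels differ and need not start at 0), control in blue and ADQ in red; diamonds are control 5, and the dash and bar are the group mean and SD (n = 5). The interferon list lies between 5.62 and 5.71 in ADQ and between 4.66 and 5.19 in control, while the rod and oxidative phosphorylation lists overlap between groups.

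With the preset correlation camera also called some lists of markers of tissue that a dissection can carry along, but none of them with an estimated correlation. Rod photoreceptor markers had a median log2 fold change of 1.24 (camera adjusted p = 1.9e-04; adjusted p = 0.648 with an estimated correlation) and cone markers 0.82 (adjusted p = 0.0351; adjusted p = 0.648 with an estimated correlation). None of either list passed over all genes; adjusted over the list alone, 1 cone marker rose. Rod markers took 0.128 ± 0.0734% of counts in control and 0.256 ± 0.172% in ADQ (SD, n = 5; exact permutation p = 0.206). Keratins of the cornea and conjunctiva were close to absent in ADQ: Krt5 was at 93.8 ± 133 CPM in control and 0.0711 ± 0.0529 in ADQ (adjusted p = 0.0846), and control 2 held 0.355 CPM. Of 7 corneal and conjunctival markers none passed over all genes, 5 fell when adjusted over the list alone, and camera gave an adjusted p of 1.3e-05 (adjusted p = 0.472 with an estimated correlation). Skeletal muscle markers had a median of -0.47 (camera adjusted p = 0.00409; adjusted p = 0.704 with an estimated correlation), none passing. ADQ 5 carried most of this: it lay at 4.28 log2 CPM against 6.03 to 6.59 in the other ADQ libraries, and without it the difference in means went from -0.54 to -0.11 and the camera adjusted p of the list: skeletal muscle markers was 0.272.

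Metabolic and pigment epithelium lists moved little. The 29 nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of -0.22, 27 of them below 0, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 9.2e-06; adjusted p = 0.648 with an estimated correlation). With the trend in transcript length as a covariate their median was -0.042 and the camera adjusted p 0.14. RPE identity markers had a median of -0.15 (adjusted p = 0.0495; adjusted p = 0.648 with an estimated correlation), and melanin synthesis genes -0.13 (adjusted p = 0.0182; adjusted p = 0.648 with an estimated correlation); no member of either passed. Both calls were lost with the same covariate, as were those of the mast cell and TGF-beta lists. Fatty acid oxidation and PPAR target genes had a median of -0.12 with 0 of 20 passing and 2 lower when adjusted over the list alone (camera adjusted p = 0.00588; adjusted p = 0.533 with an estimated correlation); Angptl4, a PPAR-induced lipase inhibitor, was at 100.4 ± 19.6 CPM in control and 57.2 ± 18.4 in ADQ (adjusted p = 0.122). TGF-beta and mesenchymal transition genes had a median of 0.15, with 1 rising when adjusted over the list alone (adjusted p = 0.0377; adjusted p = 0.533 with an estimated correlation).

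Across lists, 16 of 44 passed camera with the preset correlation, 8 higher and 8 lower. With an estimated correlation 0 did, the smallest adjusted p being 0.127. Fry called 3 (interferon, MHC class II, and cytokines and NF-kB targets), and the exact permutation test of the means called 0 after adjustment. That last outcome says little: over 44 lists even the smallest possible exact permutation p of 0.00794, reached by these 3 means, became an adjusted p of 0.0582. Among lists that did not pass, 1 glycolysis gene rose, Pfkfb3, which encodes an activator of glycolysis (1.79-fold, adjusted p = 0.00296), as did the keratan sulfate proteoglycan Kera (2.22-fold). Col4a4, a basement membrane collagen, fell 1.41-fold; without 1 library the adjusted p reached 0.144 for Kera and 0.153 for Col4a4. Pfkfb3 kept its call without any single library, and Cdk1 was the proliferation gene that fell.

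The last comparison set these calls beside the authors' own. The authors' deposited table lists 859 genes at an adjusted p under 0.05, 601 higher and 258 lower. Of the 171 genes called here, 156 are in that table and 155 were called in it, all 155 with the same direction. Log2 fold changes of the 15860 shared genes had a Pearson r of 0.937 across genes, which are not independent replicates.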

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

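In this part, the tests on control 5 and on transcript length and the comparisons with muscle markers and keratins were chosen after the results were seen, and so was the use of the rod and RPE covariates to judge an explanation, although both covariates had been fixed as alternatives before the data were examined. When the length tests were written, the trend of each library and its correlation with the fold changes were known; the tests on blood and on other splits were set before their results. Of 116 groups of 5 libraries examined, 8 held a library far from the rest, which is near the share of about 5 in 100 that chance gives. Control 1 stood apart in rod marker share (0.259% against 0.0917 to 0.096%) and in the mean of rod markers (5.89 log2 CPM against 3.70 to 4.04). Control 3 stood apart in keratin share, at 0.186% (others up to 0.0396%). ADQ 5 was low in skeletal muscle markers, at 4.28 log2 CPM (others 6.03 to 6.59). Control 5 was high in Acod1 (2.74 CPM) and Tlr12 (2.08 CPM), and ADQ 2 low in Tlr12 (3.17 CPM) and Plin1 (0.528 CPM).

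The rise of interferon and MHC class II genes was weighed against 3 technical explanations. The mean log2 fold change of the 26 members was 0.85; it was 0.97 with rod marker level as a covariate, 0.75 with erythroid marker level and 0.89 with the transcript length trend, and both lists stayed past camera with the preset correlation each time (without a covariate, adjusted p = 0.127 and 0.381 with an estimated correlation). Staying past camera adds little, since at this correlation other splits of the libraries called a median of 9 lists. The mean stayed at 0.75 or above with each covariate, which argues against more retina, more blood or a length trend as the whole cause. That the rise follows the loss of fat cells remains a hypothesis, since it was found and tested on the same libraries, and other differences between the groups stay untested.

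Oxidative phosphorylation genes were called lower only by camera with the preset correlation (adjusted p = 0.648 with an estimated correlation, fry adjusted p = 0.321). That difference may be technical. These transcripts are short (median 1521 bases against 3349 for all), and fold changes rose with length (rho 0.256 across genes). Random lists matched on length and expression had a median of -0.16, and the list's -0.22 lay at percentile 0.51, beyond the bound set before that percentile was computed by less than the matched lists' SD of 0.03; requiring a wider margin was decided after seeing it. With the RPE marker covariate the median was -0.026. A length trend and a smaller RPE share both stay open, and neither was separated from the groups here.

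Adipocyte markers had low means in ADQ and in control 5, though with all libraries none passed over all genes. Control 5 lay within the ADQ range for 36% of 353 genes (those of the 357 called without it that were also tested with all libraries), and on the ADQ side of the midpoint for 62.9%, which leaves open that it is an ADQ library under a control label, although its interferon genes were at 0.302 of the way from control to ADQ and their list mean was 5.19 log2 CPM against 5.62 to 5.71 in ADQ. The place of its adipocyte genes exceeded that of its interferon genes by 0.893, which a mixture of average control and average ADQ RNA would not give. The low adipocyte level of control 5 was known before this test, and the fat carried over may vary between samples. A mixture of control and ADQ RNA thus stays open. Less periocular tissue in ADQ also stays open. Adipocyte minus muscle means differed by -0.47 with all libraries (exact permutation p = 0.5) and by -0.90 without control 5 (exact permutation p = 0.198). Without ADQ 5, low in muscle markers, they differed by -0.87 (exact permutation p = 0.1905). Without both libraries the difference was -1.33 (exact permutation p = 0.0286, the smallest possible). Leaving out ADQ 5 was a choice made after its value was seen. Corneal and conjunctival keratins, also carried over, took 0.0492% of counts in control and 0.000108% in ADQ (exact permutation p = 0.00794, the smallest possible, adjusted 0.0714). Control 5, at 0.0396%, was unlike every ADQ library here, yet low in adipocyte markers, so keratins and adipocyte markers did not move together in it.

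Other splits of the libraries were run on 100 of the 126 possible. As many genes as the real 171 came from 2 of them, the real one included, which argues against chance for that count. The other gave 2748 genes and differs from the real grouping by exchanging control 3 and ADQ 1, which points to a structure of the samples that crosses the groups. In Gbp2 these libraries kept to their groups, at 47.2 and 169 CPM, but this gene was called by the real grouping, so that is no test of the exchange. Deviations of control 3 and ADQ 1 followed transcript length with rho of 0.199 and -0.288, each nearer to the other group's mean (-0.109 in control, 0.0956 in ADQ). For the count of lists, the other splits had a median of 9, 12 splits gave 16 or more and the highest other gave 21, so chance cannot be excluded for that count.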

How the results depend on the processing

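In this part, the length trend covariate, the joint use of a rod covariate and the omission of control 5, and the choice of 6 adipocyte markers came after the results had been seen. None of the 171 calls turned sign in any alternative of the gene test that still tested the gene. Their number was not: for genes changed, ADQ against control, it was 768 with DESeq2 (502 higher, 266 lower), 664 with voom and quality weights (511, 153), 620 with 1 surrogate variable (418, 202), 80 against a 1.2-fold change (77, 3) and 378 without control 5 and with a rod covariate (341, 37). With the RPE covariate 123 genes were called, 101 of them higher, and 89 of the 171 calls were kept. The length trend covariate kept 130 of the 171. Lower genes numbered 32 without a count filter, 41 without robust dispersion and 48 with the length trend covariate. Leaving out 1 library gave 78 to 357 genes, 69 to 316 higher and 5 to 41 lower. The cause was not tested.

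With the replicate number as a block, 694 genes were called (392 higher, 302 lower). Same-numbered samples deviated together with correlations of -0.113 to 0.163, and 1 of 5 controls correlated best with its own number, so the numbers give no pairing.

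The number of lists was 0 with an estimated correlation, 3 with fry and 0 with the exact permutation test, where even the smallest possible p did not pass after adjustment. Leaving out 1 library kept 12 to 14 of the 16 calls. RPE identity markers held in 8 of 20 alternatives and mast cell markers in 5, not counting the estimated correlation. Without control 5 the camera calls of RPE identity markers (adjusted p = 0.0784) and TGF-beta genes (0.113) were lost. The difference for targeted cells: adipocyte markers, ADQ against control was -1.42 to -0.80 when 1 library was left out, and -1.65 for the 6 markers, whose choice makes it circular. The difference was past the test without control 5, the library with the lowest level, whose omission separates the groups by itself. For the agreement with the authors' deposited comparison, shared calls numbered 311 at an adjusted p of 0.1 and 609 with voom. Signs turned for Lipe (0.0185 with the RPE covariate, 0.0379 with the length trend), for rod markers with their own covariate (adjusted p = 0.639) and for total counts (-2.15 to 2.97 M, leaving out 1 library).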

Other observations

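The test of macrophage number in this part was chosen after its result could be seen; the dendritic cell markers were listed before their values were examined. The families named here were picked because their members had been called, so their counts describe the calls and are no test. All 11 guanylate-binding proteins tested rose, with log2 fold changes from 1.40 to 3.08, and so did all 6 immunity-related GTPases (median 2.31), which defend cells against intracellular parasites. Of 10 genes of MHC class I presentation 8 rose, and 10 without control 5; Tap1, the peptide transporter, rose 3.09-fold. Cd274, which encodes the checkpoint ligand PD-L1, rose 3.05-fold. Xcr1, a chemokine receptor of cross-presenting dendritic cells, rose 4.30-fold. Despite that size it was not among the 10 named rises, so its mean was under 1 CPM or its call was lost without at least 1 library. Ifng, the interferon that induces most of these genes, was at 0.139 ± 0.194 CPM in control and 0.825 ± 0.199 in ADQ (adjusted p = 0.192).

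A hypothesis is that antigen-presenting cells are more numerous in ADQ. The MHC class II mean rose beyond the macrophage mean by 1.01 log2 units (exact permutation p = 0.00794, the smallest possible). An equal increase of all macrophages would not give this gap. More macrophages of 1 kind already present stay open, since the macrophage mean pools all kinds. Means of 8 dendritic cell markers were 1.70 ± 0.163 log2 CPM in control and 2.26 ± 0.2 in ADQ, a difference of 0.56 (exact permutation p = 0.00794). More dendritic cells may therefore contribute, but 0 of the 8 passed singly (1 without control 5), their log2 fold changes ran from -0.70 to 1.26, all 8 were also detected in controls, and induction within resident cells was not tested.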
